A study of Mus musculus with 10 samples.

How the data were processed

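The samples were cerebella of E13.5 mouse embryos, of a mixed C57BL/6 and 129 background, with 4 RNA-seq libraries of Ezh2 deletion and 4 of wild type. Per the labels' protocols, freshly dissected tissue went into RNAlater and polyadenylated RNA was sequenced by an Illumina protocol. Samples of H3K27me3 ChIP-seq, 1 per genotype, were not analysed here. Groups and replicate numbers were taken from the sample titles and descriptions.

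The authors deposited 1 table of RPKM values (reads scaled to gene length and to the mapped reads of a library), with 1 column per RNA-seq library. The submitters' processing notes name Bowtie, TopHat, SICER and Cuffdiff and the genome build mm9, without versions and for RNA-seq and ChIP-seq together. The gene annotation, the treatment of reads that map to several places and the use of strand are not given in the sources used here. Genes that share reads with near-identical copies, and overlapping or antisense genes, are therefore uncertain. The table held 22552 genes, of which 3284 were at 0 in all libraries and 4989 others lay below the level filter. In 25 rows the gene name had been turned into a date, and these genes are counted but not named. Of all names, 98.8% matched a table of RefSeq genes of assembly GRCm38.p6, which was used only for older names, chromosome class and the order of genes, and no coordinates are given since the builds differ. Among the symbols on the fixed lists, 6 were matched through older names and 1 had no match.

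RPKM values are not counts, so no count model was used and total depth is unknown. In genes with mean RPKM under 0.1, values stepped in whole reads. After scaling by relative depth, 73% of 9095 such values lay within 0.05 of a whole multiple of their gene's smallest value. Relative depth was 1, 1.26, 1.10 and 1.35 in wild type 1 to 4 and 1.56, 2.11, 1.25 and 1.69 in Ezh2 deletion 1 to 4. The sum of RPKM was 4.31e+05, 4.05e+05, 4.16e+05 and 4.26e+05 in the wild type libraries and 4.20e+05, 3.94e+05, 3.93e+05 and 4.12e+05 in the deletion libraries. Log values of 2 libraries correlated across genes with r between 0.947 and 0.967 within a genotype and between 0.94 and 0.965 across genotypes, and genes are not independent replicates. No 2 libraries held the same values. Tuba1a, an abundant gene, was listed at 0 in all libraries, and Gapdh at no more than 0.252 RPKM, so a 0 can be a failed estimate. Genes at 0 throughout a genotype are given per library, with no fold.

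Each gene with a mean of at least 0.25 RPKM over the 8 libraries was tested on log2(RPKM + 0.25) with limma 3.58.1 in R 4.3.3 (eBayes with trend and robust settings, statmod 1.5.0), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. A log2 difference is on this scale, which understates the change of low genes. Single values were compared by exact two-sided permutation over 70 arrangements, for which the smallest p is 0.0286. The 28 gene lists were fixed before the data were examined, as were the tests and the alternatives, apart from those named as chosen later. The 27 lists with at least 3 tested members were tested with camera (preset correlation 0.01), beside camera with an estimated correlation and fry. The preset test passed 15 lists, the estimated correlation 5 and fry 13. The 5 were the lists of Hox genes, CDK inhibitors, midbrain and hindbrain patterning genes, transcription factors of other neural regions and brainstem markers. The last of these shares Hoxa2 and Hoxb2 with the Hox list. Calls were also counted in 4 ranges of mean RPKM, with Fisher's exact test for the lowest range.

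The named genes followed a rule set before the data were examined. It takes Ezh2; the 10 largest rises and 10 largest falls among called genes whose 4 deletion libraries all lie on 1 side of the 4 wild type libraries and whose higher group averages at least 1 RPKM; up to 4 called members of each list with the largest change; Ptf1a, Pax2, Lhx1, Lhx5, Skor2, Gad1, Gad2, Atoh1, Pax6 and Cdkn2a whether called or not; and the most abundant member of each marker list of another cell type. It gave 72 genes, some of which are not reported here, and others are named only where this is said.

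The fit was tested on simulated data with the means and spreads of the real comparison of Ezh2 deletion with wild type, in which 14034 genes were tested. It recovered 62.7% of genes changed 1.5-fold, 89.6% of genes changed 2-fold and 98.5% of genes changed 4-fold, and 4.02% of its calls were false. Of 51 simulated lists the preset camera test called the shifted list and 0 of the unchanged ones, but the simulated genes were independent, unlike those of real lists. Alternatives covered the pseudocount, the filter, scaling, weights, the variance model, a replicate block, each library left out, removal of erythroid and Y-linked genes and Xist, and the thresholds. Added after seeing the data were a term for sex (which leaves the genotype difference to Ezh2 deletion 4), the 5 libraries with Y-linked RNA alone, removal of genes of chromosomes X and Y, of short RNA genes and of genes listed at 0 in 1 genotype, and Ezh2 deletion 1 and 2 alone. The table of the authors held no comparison columns, so the planned use of such columns was not run. Plots were made with matplotlib 3.10.9 in Python 3.11.15.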

Results

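RNA was sequenced from cerebella dissected from E13.5 mouse embryos, at mid-gestation. In the Ezh2 deletion embryos a floxed Ezh2 allele was removed by Cre recombinase expressed from Pax7, and the comparison group was wild type. Ezh2 is the main methyltransferase of Polycomb repressive complex 2, which places the silencing mark H3K27me3 on histones. There were 4 libraries per genotype, and the file gave RPKM values for 22552 genes in each of the 8 libraries. The sources do not say which libraries came from separate embryos, so p-values measure the spread between these libraries, which may be partly technical. The total number of reads per library is unknown, but the steps of 1 read in genes of low level gave relative depth. Taking wild type 1 as 1, the wild type libraries lay between 1 and 1.35, and the Ezh2 deletion libraries between 1.25 and 2.11. The mean was 1.17 ± 0.156 in wild type and 1.65 ± 0.358 in Ezh2 deletion (SD, n = 4; exact two-sided permutation p = 0.0857). H3K27me3 ChIP-seq samples, 1 per genotype, were not analysed here.

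The first comparison checked the deleted gene itself. Ezh2 RNA was 78.7 ± 4.54 RPKM in wild type and 54.5 ± 6.91 RPKM in Ezh2 deletion (SD, n = 4), 69.3% of the wild type level. The wild type libraries 1 to 4 held 73.6, 84.7, 78.2 and 78.2 RPKM, and the Ezh2 deletion libraries 53.8, 48.7, 51.1 and 64.4 RPKM, so each deletion library lay below each wild type library. The log2 difference was -0.53 (SE 0.084, limma adjusted p = 0.0074). The exact two-sided permutation test over 70 arrangements gave p = 0.0286, the smallest it can give with 4 libraries against 4. A value per gene does not show which exons remained, and reads from exons outside the deleted part count towards it. In Ezh2 deletion 4 against the 4 wild type libraries, the only comparison within libraries carrying Y-linked RNA, the difference was -0.29 and did not pass (limma adjusted p = 0.146). That test takes its spread from wild type alone and assumes that the single deletion library varies alike.

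The next comparison asked which genes differed between Ezh2 deletion and wild type cerebellum. Genes of the Hox clusters and Cdkn2a rose from values near 0, some transcription factors of other body regions were also higher, and genes of Purkinje cells, Olig1 and Olig2 were among those that fell. Of 14279 genes tested, 387 were higher and 106 lower in Ezh2 deletion (limma, adjusted p under 0.05). A change of at least 2-fold was found for 124 of the higher and 9 of the lower genes. Of the 387 higher genes, 15 were listed at 0 in all wild type libraries, and 109 of the 124 remained when such genes were set aside. The median log2 difference was 0.75 for the higher genes and -0.48 for the lower genes. With 1 library left out there were 244 higher and 47 lower genes without wild type 3, 223 and 40 without wild type 4, and 227 and 47 without Ezh2 deletion 3. The lower genes also numbered 62 without wild type 1, 55 without wild type 2 and 70 without Ezh2 deletion 1, and the genes lower at least 2-fold numbered 19 without Ezh2 deletion 2. Higher genes made up 78.5% of calls, and 89.8% (478 higher, 54 lower) when erythroid and Y-linked genes and Xist were removed and the libraries rescaled.

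The genotypes also differed in markers of sex, which the labels do not give. Xist, the RNA of the inactive X chromosome, was at 54.1, 62.8 and 94.5 RPKM in Ezh2 deletion 1, 2 and 3, at 0.094 RPKM in Ezh2 deletion 4, and at most 0.0712 RPKM in wild type. The Y-linked gene Ddx3y was between 8.31 and 9.43 RPKM in wild type and at 7.92 RPKM in Ezh2 deletion 4, and at most 0.0219 RPKM in Ezh2 deletion 1 to 3. A term for sex was chosen after seeing these values. It takes up the difference between Ezh2 deletion 1 to 3 and Ezh2 deletion 4, so the genotype difference fitted beside it is that of 1 library, Ezh2 deletion 4, against wild type, and is no adjustment over all libraries. In that fit 276 genes were higher and 232 lower, and 175 higher and 58 lower genes were shared with the fit without the term. All 387 higher and 106 lower genes kept their sign in Ezh2 deletion 4, with median log2 differences of 0.75 and -0.56, though they were selected on libraries that include it.

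**Figure D1:**
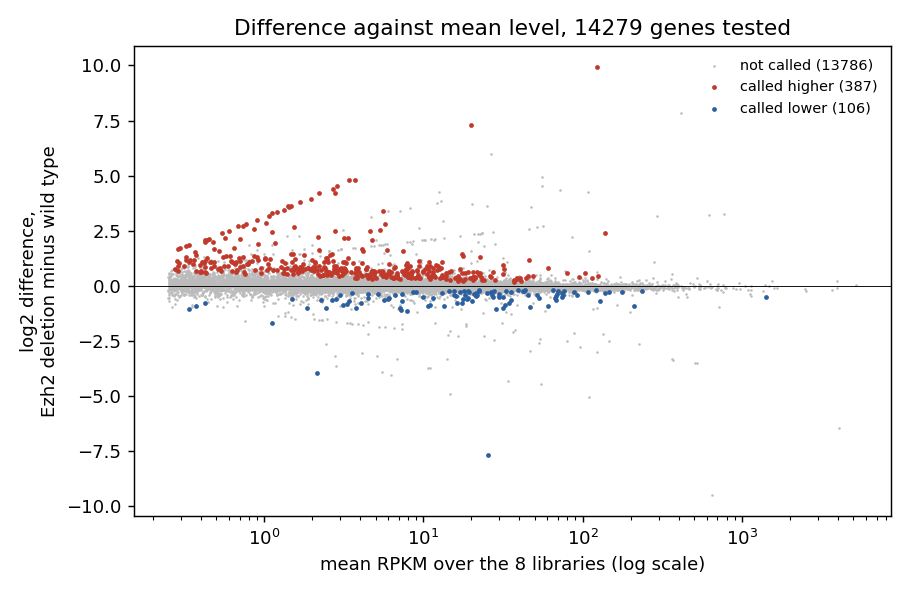
Log2 difference between Ezh2 deletion and wild type (y axis, on the log2(RPKM + 0.25) scale) against the mean RPKM over the 8 libraries (x axis, log scale) for the 14279 genes tested, 1 point per gene. The 387 genes called higher lie mostly at low mean levels, and the 106 genes called lower mostly at higher ones.

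Among called genes, those of low mean level were mostly higher in Ezh2 deletion. In the range of 0.25 to 1 RPKM, 86 genes were higher and 3 lower, and the counts were 147 and 17 from 1 to 5 RPKM, 115 and 32 from 5 to 20 RPKM, and 39 and 54 above 20 RPKM. Higher genes thus made up 96.6% of calls in the lowest range and 74.5% in the other ranges together (Fisher's exact test, two-sided, p = 2.9e-07). With quantile normalization the difference between these shares was 8.25 percentage points and did not pass (Fisher's exact test, p = 0.176). When erythroid and Y-linked genes and Xist were removed and the libraries rescaled, it was 8.81 points and passed (Fisher's exact test, p = 0.0056). Fisher's test counts genes as independent, while genes such as those of the Hox clusters changed together. Its p therefore does not measure the spread between libraries.

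Hox genes, which set position along the body axis and were near 0 in wild type cerebellum here, showed the clearest change. All 39 were listed, 26 passed the level filter, and 25 of these 26 were higher in Ezh2 deletion and 0 lower. Adjusted over the list alone, 26 were higher. Hoxb8 was 0.0229 ± 0.0188 RPKM in wild type and 7.37 ± 1.10 RPKM in Ezh2 deletion (SD, n = 4), a log2 difference of 4.79 (SE 0.133, limma adjusted p = 3.69e-08). Hoxc9 went from 0.005 to 5.70 RPKM and Hoxa5 from 0.0497 to 5.52 RPKM. Hoxb7 was listed at 0 in all 4 wild type libraries and at 4.49, 5.30, 3.86 and 3.91 RPKM in Ezh2 deletion 1 to 4. All 4 clusters took part. Higher were 8 of 8 tested genes in cluster A (11 members), 8 of 8 in B (10), 4 of 4 in C (9) and 5 of 6 in D (9). Not called was Hoxd13, at 0.217 RPKM in wild type and 0.416 RPKM in Ezh2 deletion. With wild type near 0, a Hox gene passed the level filter mainly through its deletion level. Counts and list tests over tested members are therefore tilted towards higher genes. Of the 13 genes below the filter, 7 had all deletion libraries above all wild type libraries and 0 all below. Mean levels reached 1 RPKM in 18 Hox genes in Ezh2 deletion and in 0 in wild type, where the highest mean was 0.276 RPKM, of Hoxa2. Over the 39 genes, the 4 deletion libraries lay above the 4 wild type libraries in 33, where chance puts 4 libraries apart from 4 in 2.86% of genes in either direction. The median log2 difference of the tested members was 3.08, and 3.19 over those not listed at 0 throughout a genotype. The list passed the camera test (adjusted p = 3.61e-60, and adjusted p = 0.0176 with an estimated correlation).

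**Figure D2:**
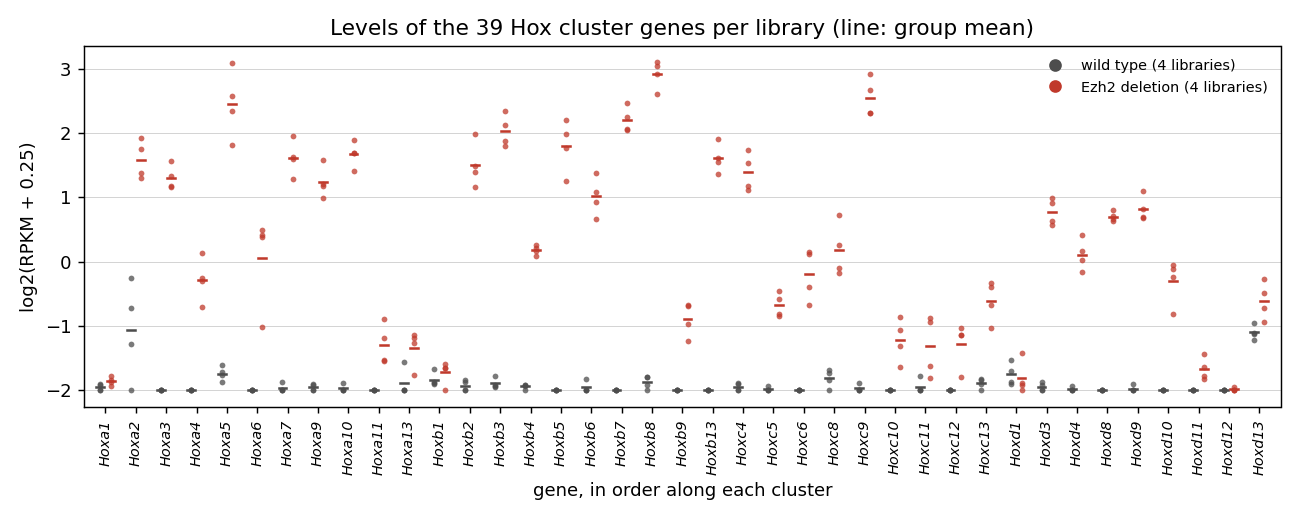
Levels of the 39 Hox genes on the log2(RPKM + 0.25) scale (y axis), by gene in cluster order (x axis). Each point is 1 library, grey for wild type and red for Ezh2 deletion, and lines mark group means; wild type values sit near the floor of the scale, and the red points of Hoxb8, the highest gene by mean level, average 7.37 RPKM.

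The cell cycle inhibitors of the CDK family gave a second group. Of 7 tested, Cdkn2a and Cdkn2b were higher and 0 were lower (3 higher when adjusted over the list alone). Cdkn2a, which encodes p16 and p19 and is a textbook Polycomb target, went from 0.0139 ± 0.0279 to 5.42 ± 1.92 RPKM (SD, n = 4), a log2 difference of 4.38 (SE 0.208, limma adjusted p = 1.72e-06). Cdkn2b, the adjacent inhibitor gene, went from 0.186 to 2.06 RPKM. The list passed camera (adjusted p = 2.75e-05, and adjusted p = 0.0394 with an estimated correlation). Of 23 cell cycle genes only Ccnd2, a D-type cyclin, was called, from 82.3 to 123 RPKM, and the list, with a median log2 difference of 0.17, had camera adjusted p = 3e-04, and adjusted p = 0.602 with an estimated correlation. Leaving out 1 library moved that median between 0.067 and 0.25. Ccnd2 was not called without wild type 3, wild type 4 or Ezh2 deletion 3.

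Some transcription factors of other tissues were also higher. Of 25 tested factors of other neural regions 9 were higher and 0 lower (13 higher adjusted over the list alone), and the list passed camera with a preset and with an estimated correlation (adjusted p = 1.13e-12 and 0.0176). Hmx3, a factor of the inner ear and hypothalamus, went from 0.0612 to 1.65 RPKM. Hmx2 was listed at 0 in wild type and at 0.828, 0.705, 0.486 and 0.669 RPKM in the deletion libraries. Vax2, a factor of the ventral eye named for the size of its change, was listed at 0 in wild type and at 6.65, 8.03, 5.25 and 7.20 RPKM in the deletion libraries. Of 20 tested factors of non-neural lineages 8 were higher and 0 lower (11 higher adjusted over the list alone; camera adjusted p = 3e-10, and adjusted p = 0.0509 with an estimated correlation). Among them Twist1, a mesenchymal factor, went from 0.752 ± 0.206 to 10.3 ± 2.18 RPKM (SD, n = 4), Shox2 from 1.48 to 9.24 RPKM and Foxd3, a neural crest factor, from 0.0523 to 2.00 RPKM. Hand2 was listed at 0 in wild type and at 1.64, 1.49, 0.861 and 0.836 RPKM in the deletion libraries.

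The series title concerns the fate of GABAergic neurons, and several lists cover their lineage. Among 6 genes of interneuron precursors Pax2 and Pax8 were higher and 0 lower (3 higher adjusted over the list alone). Pax2, the usual marker of these precursors, went from 8.18 ± 0.677 to 15.8 ± 1.51 RPKM (SD, n = 4), a log2 difference of 0.93 (SE 0.084, limma adjusted p = 2.5e-04), and Pax8 from 1.29 to 7.91 RPKM. The list passed camera (adjusted p = 1.2e-04), with adjusted p = 0.0904 with an estimated correlation. Pax2, Pax5 and Pax8 are also on the list of genes that pattern the border of midbrain and hindbrain. Markers of the midbrain had a median log2 difference of 1.13 in the same libraries. Among 22 genes of Purkinje cells, the output neurons of the cerebellar cortex, 7 were lower and 1 higher (11 lower and 1 higher adjusted over the list alone). Slc1a6, a glutamate transporter of Purkinje cells, fell from 9.96 ± 0.565 to 4.54 ± 0.238 RPKM (SD, n = 4), a log2 difference of -1.09 (SE 0.069, limma adjusted p = 1.47e-05). Skor2, a transcriptional corepressor of young Purkinje cells, fell from 61.7 to 32.2 RPKM, Etv1 from 9.51 to 4.77 RPKM and Pcp4 from 271 to 147 RPKM. The higher gene was Plcb3, from 7.81 to 10.5 RPKM. The list's median log2 difference was -0.38 (camera adjusted p = 1.76e-05, and adjusted p = 0.144 with an estimated correlation). Its mean level gave an exact permutation p = 0.0286, the smallest possible and one that 13 of the 27 lists tested reached, stress genes included. With a term for sex, where Ezh2 deletion 4 is the only deletion library compared, Skor2 had a log2 difference of -1.07 and was not called (limma adjusted p = 0.0586, SE 0.237 against 0.143 with all 4 libraries). Pcp4 was not called when any 1 library other than Ezh2 deletion 2 was left out.

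Other genes of the GABAergic lineage did not pass. Ptf1a, the factor that specifies GABAergic progenitors of the cerebellum, was 4.35 ± 0.527 RPKM in wild type and 2.94 ± 0.789 RPKM in Ezh2 deletion (SD, n = 4; limma adjusted p = 0.125). Lhx1 was at 81.6 and 63.5 RPKM and Lhx5 at 72.6 and 63.7 RPKM. Gad1 and Gad2, which make GABA, were at 24.1 and 31.3 RPKM in wild type and at 23.5 and 28.4 RPKM in Ezh2 deletion. Of 11 progenitor genes only Olig2, a factor of Purkinje progenitors, was called, and it fell from 14 to 7.45 RPKM (limma adjusted p = 5.1e-05). Of 5 genes for GABA synthesis and transport only Abat, which degrades GABA, was called, from 38.1 to 44.2 RPKM, and it was not called when any 1 library was left out. Neither list passed camera (adjusted p = 0.19 and 0.599), though the progenitor list passed without wild type 1 or Ezh2 deletion 4 (adjusted p = 0.038 and 0.0316).

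**Figure D3:**
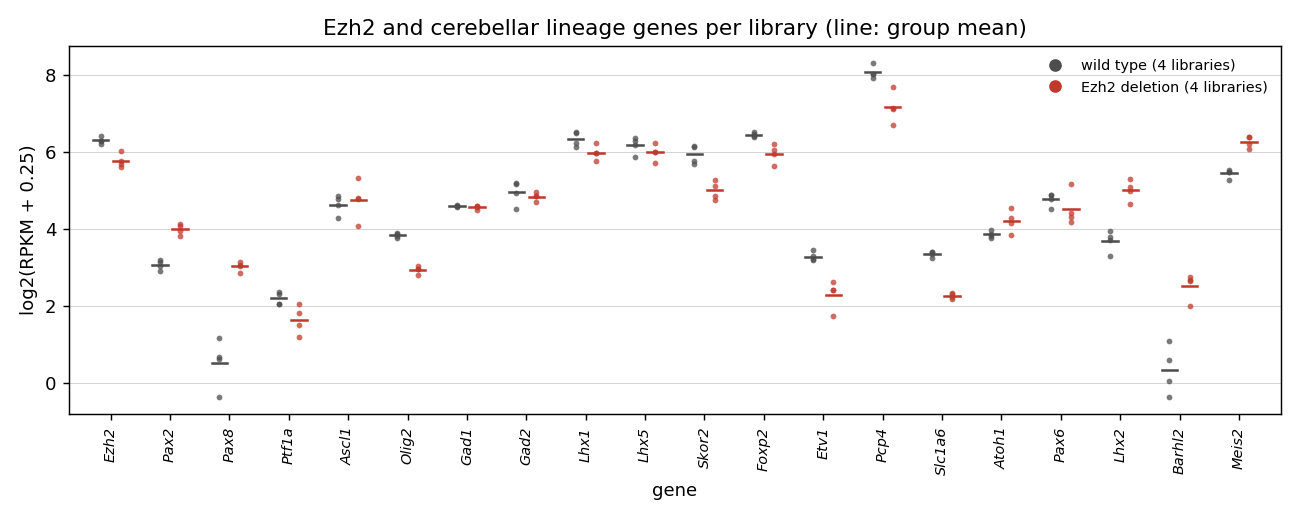
Levels of Ezh2 and of cerebellar lineage genes on the log2(RPKM + 0.25) scale (y axis) by gene (x axis), 1 point per library, grey for wild type and red for Ezh2 deletion, with lines at group means. Pax2 and Pax8 lie higher and Skor2, Etv1, Pcp4 and Slc1a6 lower in all 4 deletion libraries, while the points of Gad1, Gad2 and Lhx5 overlap.

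Glutamatergic and patterning genes were followed as well. Of 22 genes of the rhombic lip, the source of glutamatergic cerebellar neurons, 4 were higher and 0 lower, both over all genes and adjusted over the list alone. These were Barhl2, from 1.12 to 5.57 RPKM, Lhx2, from 12.7 to 32.3 RPKM, Meis2, from 43.3 to 76.8 RPKM, and Slc17a6, a vesicular glutamate transporter, from 25.7 to 37.6 RPKM. Atoh1, the defining factor of the rhombic lip, was at 14.3 and 18.5 RPKM and Pax6 at 27.2 and 23.5 RPKM, and neither passed (limma adjusted p = 0.19 and 0.571). The list had camera adjusted p = 0.0042, and adjusted p = 0.184 with an estimated correlation, and did not pass the preset test without Ezh2 deletion 2. Its median log2 difference was 0.15 over all libraries and 0.048 with a term for sex. With a term for sex, and so in Ezh2 deletion 4 alone, Barhl2 and Lmx1b had log2 differences of 2.40 (SE 0.518) and 1.05 (SE 0.316), against 2.17 (SE 0.309) and 1.45 (SE 0.22) over all 4 libraries, and were not called. Ezh2 deletion 4 held the lowest Lmx1b level of the deletion libraries, 18.9 RPKM. Of 14 genes that pattern the border of midbrain and hindbrain, 4 were higher and 0 lower (8 higher adjusted over the list alone). They were Pax2, Pax8, Lmx1b, from 9.33 to 25.4 RPKM, and Spry1, an inhibitor of FGF signalling, from 8.98 to 15.3 RPKM. That list passed camera (adjusted p = 2.9e-07, and adjusted p = 0.0476 with an estimated correlation), with a median log2 difference of 0.83. It includes Otx2, a midbrain gene named after its values were seen, which was at 5.45 ± 2.06 RPKM in wild type and 13.8 ± 7.05 RPKM in Ezh2 deletion (SD, n = 4) and was not called (limma adjusted p = 0.338). The markers of the neighbouring midbrain, described below, had a median of 1.13, and how much midbrain tissue each sample held is unknown.

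Among the Polycomb genes, 1 of 11 subunits of repressive complex 2 was called, which was Ezh2 itself. Of 19 subunits of repressive complex 1, Bmi1 was higher and 0 were lower (3 higher adjusted over the list alone; camera adjusted p = 0.0587, and under 0.05 without wild type 3, wild type 4 or Ezh2 deletion 2). Bmi1 went from 28.3 ± 1.76 to 63.6 ± 4.98 RPKM (SD, n = 4), a log2 difference of 1.16 (SE 0.068, limma adjusted p = 7.68e-06). Its neighbour Commd3, chosen after its values were seen, went from 106 to 145 RPKM.

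Genes with smaller or mixed changes filled the remaining lists. Of 11 tested p53 targets Eda2r, Pmaip1, Phlda3 and Sesn2 were higher (5 adjusted over the list alone), with Pmaip1, which promotes apoptosis, from 1.60 to 3.80 RPKM and Phlda3 from 2.63 to 4.87 RPKM (camera adjusted p = 0.0016, and adjusted p = 0.077 with an estimated correlation). Of 11 imprinted genes Dlk1 and Plagl1 were higher, from 12.3 to 21.4 RPKM and from 15.0 to 23.2 RPKM (camera adjusted p = 0.0072, and adjusted p = 0.077 with an estimated correlation). With a term for sex, and so in Ezh2 deletion 4 alone, Dlk1 was not called (log2 difference 0.70, SE 0.193, against 0.78, SE 0.118, over all 4 libraries), and the imprinted list, with a median of 0.015 against 0.14, did not pass (camera adjusted p = 0.178). Of 14 progenitor genes Hes1 was higher, from 10.9 to 15.4 RPKM, and Fabp7, a lipid carrier of radial glia, lower, from 1661 to 1182 RPKM (camera adjusted p = 0.0102, and adjusted p = 0.412 with an estimated correlation). Hes1 was not called without wild type 1, 3 or 4 or Ezh2 deletion 2, 3 or 4, Eda2r not without wild type 1, 3 or 4 or Ezh2 deletion 1 or 3, and Sesn2 not without wild type 2 or 4 or Ezh2 deletion 2, 3 or 4. The progenitor list did not pass the preset camera test without Ezh2 deletion 4. None of 13 genes of neuronal differentiation was called by limma (4 with an unadjusted p under 0.05; 1 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.0844, and adjusted p = 0.0382 without wild type 3 and 0.0083 without Ezh2 deletion 1). Apart from Tuba1b and Tuba1c, described below, the largest falls outside the lists, among called genes whose deletion libraries all lay below the wild type libraries and that held at least 1 RPKM in wild type, were those of Ucma, from 1.82 to 0.421 RPKM, the cation channel genes Trpc4, from 11 to 4.83 RPKM, and Trpc7, from 3.32 to 1.57 RPKM, the nuclear receptor gene Esrrb, from 38.1 to 18.8 RPKM, Olig1, from 5.19 to 2.39 RPKM, Nrp2, from 41.7 to 21.3 RPKM, and Arhgap15, from 2.55 to 1.17 RPKM. Trpc7 was not called when any 1 library other than Ezh2 deletion 2 was left out, and Nrp2 was not called when any 1 wild type library or Ezh2 deletion 1 was left out.

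The fitted changes of the largest size belonged to genes whose estimates are uncertain. Snord57, a small nucleolar RNA, was listed at 0 in all wild type libraries and at 250, 185, 314 and 232 RPKM in Ezh2 deletion 1 to 4, and Mir453, a microRNA, at 0 and at 40.3, 29.9, 50.6 and 37.4 RPKM. Tuba1b was at 55.8, 57.9, 42.5 and 48.5 RPKM in wild type 1 to 4 and listed at 0 in all deletion libraries, and Tuba1c at 1.05, 6.91, 4.99 and 4.18 RPKM and at 0. Tuba1a, a near-identical tubulin gene that neural cells express strongly, was listed at 0 in all 8 libraries.

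Markers of other cell types showed few calls, which does not show that tissue composition was alike. Some were high in single deletion libraries, as described below. Median log2 differences were 0.90 for choroid plexus, 0.74 for mesenchymal, 0.89 for brainstem, 0.17 for microglial and 0.071 for endothelial markers. They were -0.14 for mural and -0.088 for erythroid markers. None of 10 endothelial, 6 mural or 10 microglial and macrophage genes was called by limma (camera adjusted p = 0.461, 0.385 and 0.144), nor any of 10 choroid plexus genes, 8 tested stress genes and 11 tested housekeeping genes (camera adjusted p = 0.0977, 0.23 and 0.699). Some of these lists passed the preset test in other settings. The choroid plexus list passed without Ezh2 deletion 3 or 4 (adjusted p = 0.0244 and 0.0146) and with Ezh2 deletion 1 and 2 alone (adjusted p = 7.6e-05, median log2 difference 1.29), and its median was -0.066 without Ezh2 deletion 2. The microglial list passed without wild type 2 or Ezh2 deletion 4 (adjusted p = 0.0342 and 0.0422), and the endothelial list without Ezh2 deletion 4 (adjusted p = 0.0428). An unadjusted p under 0.05 was found for 0 endothelial, 0 mural, 2 microglial and macrophage, 0 choroid plexus, 1 stress and 3 housekeeping genes, and for 2528 of all genes tested. The most abundant markers were Cldn5 of endothelium, at 26.4 and 22.5 RPKM in wild type and Ezh2 deletion, Rgs5 of mural cells, at 20.3 and 16.7 RPKM, C1qb of microglia, at 5.20 and 5.96 RPKM, Lmx1a, a choroid plexus marker that the rhombic lip also expresses, at 26.0 and 25.9 RPKM, and Hbb-y of red cells, at 307 and 408 RPKM. Of 10 tested erythroid genes the globin gene Beta-s was lower, from 41.4 to 23.1 RPKM (camera adjusted p = 0.286, and adjusted p = 0.0315 without Ezh2 deletion 4), and it was not called when any 1 wild type library or Ezh2 deletion 1 or 2 was left out. Of 8 tested mesenchymal genes Twist1 was higher, and of 2 tested neural crest genes Foxd3. The mesenchymal list had camera adjusted p = 0.0069, and adjusted p = 0.482 with an estimated correlation and 0.11 with fry. It did not pass the preset test without Ezh2 deletion 2. With a term for sex, and so in Ezh2 deletion 4 alone, its median was 0.050. Of 8 tested midbrain genes Pou4f1 was higher, from 6.80 to 14.9 RPKM (4 adjusted over the list alone; median log2 difference 1.13; camera adjusted p = 5.5e-05, and adjusted p = 0.0904 with an estimated correlation). Of 5 tested brainstem genes Hoxa2, Hoxb2 and Slc6a4 were higher (4 adjusted over the list alone; camera adjusted p = 1.22e-05, and adjusted p = 0.0394 with an estimated correlation). Slc6a4, at 0.126 and 0.445 RPKM, was called without Ezh2 deletion 1 and lost when any other library was left out.

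Single libraries stood apart in some of these markers. Ttr, the main transcript of the choroid plexus, was at 152 RPKM in Ezh2 deletion 2, 16.2 RPKM in Ezh2 deletion 1 and at most 5.0 RPKM in the other libraries. Otx1, a midbrain factor named after its values were seen, was at 0.364, 1.05, 2.52 and 3.95 RPKM in Ezh2 deletion 1 to 4 and at most 0.662 RPKM in wild type. Tal2, another, was at 9.02 RPKM in Ezh2 deletion 3, 26.6 RPKM in Ezh2 deletion 4 and at most 1.44 RPKM elsewhere. Without Ezh2 deletion 2, 302 genes were higher and 100 lower, and with Ezh2 deletion 1 and 2 alone against wild type, a setting chosen after seeing the data, 168 were higher and 44 lower.

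**Figure D4:**
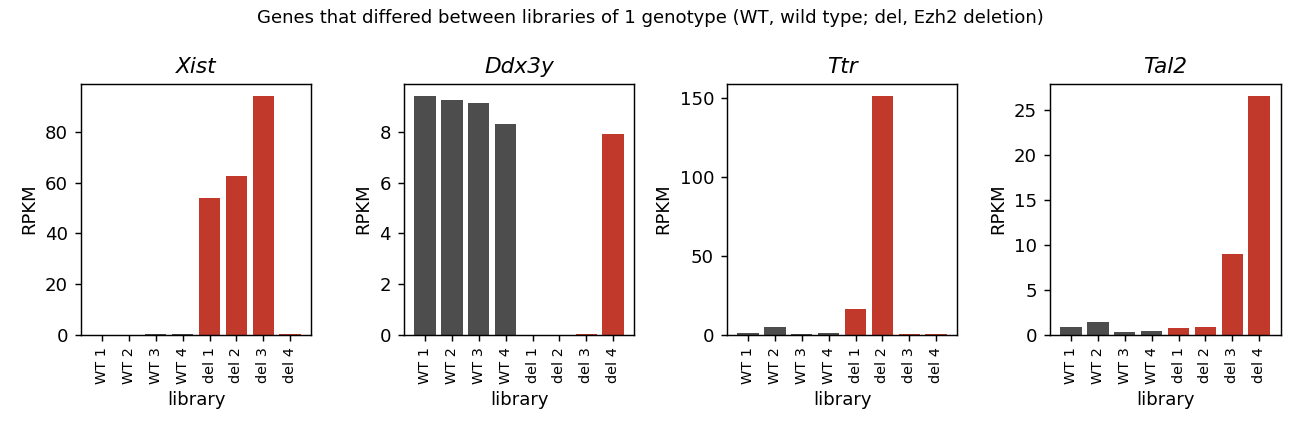
RPKM (y axis, linear, from 0) of Xist, Ddx3y, Ttr and Tal2 in each library (x axis), 1 bar per library, grey for wild type and red for Ezh2 deletion. Xist and Ddx3y part Ezh2 deletion 1 to 3 from the other 5 libraries, Ttr is highest in Ezh2 deletion 2 at 152 RPKM, and Tal2 in Ezh2 deletion 4 at 26.6 RPKM.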

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

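All tests of explanations in this part were chosen after the results were seen, except the counts over other splits of the libraries with the preset list test. The 8 libraries can be split into 4 and 4 in 35 ways. For the 493 genes called in either direction, 1 split, the real one, gave as many, and the highest of the others gave 13. The same held for the 387 calls in the larger direction (1 split, highest other 9) and the 106 in the smaller (1 split, highest other 4). It also held for the 133 changes of at least 2-fold (1 split, highest other 4). The real split thus ranked first of 35, the most that so few splits can show. The other splits mix the genotypes, which widens their spread and lowers their counts. For the 15 lists past camera with a preset correlation the real split did not stand out, since 6 splits gave as many and the highest other gave 16. The other splits among these kept 3 libraries of each genotype together. They hold part of the genotype difference and are no measure of chance. Splits with 2 libraries of each genotype on each side passed at most 9 lists. The preset test thus passes lists even where the genotypes are balanced, so its p-values are too small here. With an estimated correlation 5 lists passed, and 1 split, the real one, gave as many, with 0 in each of the others. For the share of higher calls at low levels the other splits called too few genes to give a value, and only 1 split, the real one, could be used.

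The first pattern weighed is the set of calls itself, since sex and genotype overlap. If X-linked genes made up the calls, chromosomes X and Y would be overrepresented. They held 2.03% of called genes and 3.63% of the other tested genes (Fisher's exact test, p = 0.0631), so they were not. This does not weigh on sex as a cause. A gene that differs by sex is hard to call here, because Ezh2 deletion 4 then departs from the other deletion libraries. Xist and Ddx3y themselves were not called (log2 differences 6.00 and -3.92, limma adjusted p = 0.178 and 0.172). Genes were also called in Ezh2 deletion 1 to 3 against wild type 1 and 2 and then measured in Ezh2 deletion 4 against wild type 3 and 4, which all carry Y-linked RNA. The 143 higher genes had a median log2 difference of 1.22 in the first set and 1.09 in the second, with 141 of 143 higher, and 28 of 31 lower genes were again lower. Because only 1 deletion library carries Y-linked RNA, a part played by sex cannot be told apart from genotype for the calls as a whole, and the genotype remains open as the biological explanation.

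The second pattern is the rise of Hox genes. Deeper sequencing of the deletion libraries cannot account for it: over the 21 Hox genes whose values resolve into whole reads, counting the smallest value as 1 read, 59 reads fell in wild type and 11449 in Ezh2 deletion, 138 times the ratio expected from depth (1.41). More brainstem tissue in the deletion samples and an effect of the deletion itself both stay open, and no test between them is reported here.

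The third pattern is the size of the changes of Snord57, Mir453 and Tuba1b. Multiplied by relative depth, the values of both short RNAs, 2 of 2, were the same in all 4 deletion libraries within 0.1%. Of 16107 genes above 0 in all deletion libraries, 11 showed this, which fits a fixed or minimal number of reads rather than independent counts. For the tubulin genes, Tuba1a was listed at 0 in 8 of 8 libraries, which would go with failed estimates for this family. Tuba1a was at 0 in both genotypes, so it does not show why Tuba1b and Tuba1c were at 0 in the deletion libraries alone. Why the values of these tubulin genes and short RNAs split by genotype was not tested. Other genes listed at 0 throughout 1 genotype could be affected alike. No biological explanation was tested for Snord57, Mir453 and the tubulin genes.

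Single libraries far from the other 3 of their group were found in 21 of 204 groups of values, where chance gives about 10.2. The groups included sex-linked genes, among them Xist and Ddx3y, in which Ezh2 deletion 4 differs as described above. Some other flags rest on values near 0, such as Hoxc9, at 1 read in wild type 4 and 0 in the other wild type libraries. The excess over chance is therefore partly built in. The sex-linked genes in Ezh2 deletion 4 were at 0.094 RPKM for Xist, 7.92 for Ddx3y, 8.94 for Kdm5d, 21.7 for Eif2s3y and 4.12 for Uty. In Ezh2 deletion 2, Ucma was high at 0.856 RPKM, C1qb high at 9.26 RPKM and Barhl2 low at 3.73 RPKM, and mean log2 levels were high for p53 targets (3.44), microglia and macrophage markers (1.82) and meningeal and mesenchymal markers (1.81). In Ezh2 deletion 4, Lmx1b was low at 18.9 RPKM and the mean log2 level of GABA synthesis and transport genes low at 4.70. In wild type 1, Spry1 was low at 7.70 RPKM, Fabp7 high at 1763 RPKM, Cdkn2a high at 0.0557 RPKM and the mean log2 level of interneuron precursor genes low at 3.00. In wild type 2, Hoxb3 was high at 0.0414 RPKM and the mean log2 level of endothelial markers high at 2.66. In wild type 4, Hoxc9 was high at 0.0198 RPKM and Dlk1 high at 15.1 RPKM.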

How the results depend on the processing

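Settings that concern sex, X and Y genes, short RNA genes, genes listed at 0 or Ezh2 deletion 1 and 2 alone were chosen after seeing the data. Where a value moved, the cause was not tested, unless fewer libraries or genes or another threshold show it. Higher genes numbered 195 with only the libraries carrying Y-linked RNA, 168 with Ezh2 deletion 1 and 2 alone, 173 at adjusted p under 0.01 and 614 under 0.1. Lower genes numbered 181 with array weights, 54 after removal of erythroid and Y-linked genes and Xist, 232 with a term for sex, 44 with Ezh2 deletion 1 and 2 alone, 28 at adjusted p under 0.01 and 248 under 0.1. Genes higher at least 2-fold numbered 56 with pseudocount 1 and 69 with a filter of 1 RPKM. Genes lower at least 2-fold numbered 14 with pseudocount 0.05, 4 with pseudocount 1, 15 with quantile normalization, 47 with a term for sex and 40 with only the libraries carrying Y-linked RNA. The log2 difference of Ezh2 was -0.29 with a term for sex and with only those libraries, and did not pass in either. Both settings compare Ezh2 deletion 4 alone with wild type. The share of higher calls differed between the lowest range and the rest by 8.25 percentage points with quantile normalization. It differed by 8.81 points after removal of erythroid and Y-linked genes and Xist, and a filter of 1 RPKM leaves no lowest range. The estimated correlation passed 5 lists. Lists that passed only in other settings, besides 1 library left out, were those of repressive complex 1 (a filter of 1 RPKM, quantile normalization, replicate block, removal of erythroid and Y-linked genes and Xist, both settings for sex, and fry), microglia (a filter of 1 RPKM, replicate block, Ezh2 deletion 1 and 2 alone), GABAergic progenitors (that removal, Ezh2 deletion 1 and 2 alone), endothelium (libraries with Y-linked RNA, with the sign changed, and Ezh2 deletion 1 and 2 alone), choroid plexus (Ezh2 deletion 1 and 2 alone), and mural and neuronal differentiation genes (both settings for sex).

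The replicate block gave 300 higher and 53 lower genes. Deviations of libraries with the same number correlated at 0.0034, 0.0867, 0.0633 and 0.0521, and none of these matches was the best in both directions. The values gave no sign that the numbers pair the libraries, but so few libraries cannot exclude it.

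Leaving out 1 library at a time gave 223 to 352 higher and 40 to 100 lower genes, 106 to 133 and 7 to 19 at least 2-fold, an Ezh2 difference of -0.62 to -0.48, 14 to 19 lists and a difference in shares of 11.8 to 27.3 points. Values that changed sign ranged from -0.38 to 0.15 for the median of GABAergic progenitor genes, -0.045 to 0.059 for GABA synthesis, -0.31 to 0.082 for erythroid, -0.20 to 0.024 for mural, -0.066 to 1.01 for choroid plexus and -0.0016 to 0.036 for housekeeping genes, and from -0.047 to 0.30 for C1qb and -0.066 to 0.054 for Lmx1a.

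Other changes of sign were these log2 values, none in a called gene and, among lists past the preset test, only in cell cycle genes. Quantile normalization gave -0.012 for stress genes and 0.023 for Lmx1a, and array weights 0.024 for GABA synthesis. Removal of erythroid and Y-linked genes and Xist gave 0.031 for repressive complex 2, 0.021 for GABA synthesis, 0.017 for Gad1 and 0.042 for Lmx1a. A term for sex gave 0.031 for repressive complex 2, 0.36 for GABAergic progenitors, 0.56 for erythroid, -0.19 for endothelial, -0.21 for choroid plexus and -0.059 for stress genes, and -0.086 for C1qb. The libraries carrying Y-linked RNA alone gave those values again, apart from 0.80 for erythroid and -0.23 for choroid plexus. Without genes of chromosomes X and Y the erythroid median was 0.17. Ezh2 deletion 1 and 2 alone gave 0.065 for GABA synthesis, -0.041 for cell cycle genes, 0.0049 for mural genes, 0.018 for Pax6 and 0.13 for Lmx1a.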

Other observations

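The lists in the first paragraph, and their tests, were chosen after the results were seen; the test of neighbouring genes was written before its result. Genes of MHC class I antigen presentation were among those higher in Ezh2 deletion. Of 13 tested, 5 were higher and 0 lower: H2-K1, from 5.24 ± 0.759 to 10.3 ± 1.71 RPKM (SD, n = 4), H2-D1, from 9.91 to 12.2 RPKM, H2-Q7, from 0.361 to 0.946 RPKM, and the peptide transporter and proteasome genes Tap1 and Psmb8, from 0.172 to 0.643 and from 0.221 to 0.884 RPKM. The list passed camera with an estimated correlation (adjusted p = 0.0229). An interferon response was tested as an explanation, and 0 of 14 interferon genes were called by limma (1 with an unadjusted p under 0.05), with a list adjusted p = 0.54, which leaves it open. Epithelial junction and keratinocyte genes formed another group, with 8 of 13 higher and 0 lower (adjusted p = 0.0146 with an estimated correlation). Epcam, an epithelial adhesion gene, went from 1.30 ± 0.223 to 3.88 ± 1.02 RPKM, Cldn3 from 0.306 to 1.09 RPKM, Cdh1 from 0.33 to 0.998 RPKM and Ripk4 from 0.0991 to 0.875 RPKM. Both lists were built from genes already seen to be high, so these tests describe the groups and are not independent evidence.

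A hypothesis set out before its test was that genes outside the Hox clusters rise together with their neighbours. In the order of the 14137 tested genes on GRCm38.p6 without Hox genes, 23 pairs of neighbouring genes were both called higher, against a median of 9 and a highest value of 21 in 10000 random sets matched on level (permutation p = 1e-04, the smallest these sets can give). The pairs included Cdkn2a and Cdkn2b, Hmx3 and Hmx2, Tap1 and Psmb8, Mt2 and Mt1, Foxl2os and Foxl2, and Commd3 and Bmi1. This is consistent with regions of several genes changing as units, but shared reads between overlapping or similar genes could add pairs, as for Foxl2os and Foxl2, and were not tested.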
